A study of Mus musculus with 3 samples.

How the data were processed

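Single-cell RNA sequencing was carried out on sorted mouse bone marrow LSK cells, the lineage-negative, Sca-1-positive, Kit-positive fraction that holds haematopoietic stem cells and multipotent progenitors. There were 3 Chromium 3' v2 libraries, 1 for each genotype: wild type (WT), Spop deleted (KO, with Myd88 intact) and Spop deleted with Myd88 absent (DKO). The submitters' processing notes name bcl2fastq, Cell Ranger, Seurat and the mm10 build, and the roles and versions of these tools were not used here.

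The deposited count table holds whole-number UMI counts for 14721 genes in 21251 cells that the authors kept. The deposited normalized table holds the natural log of 1 plus 10000 times each gene's count over the cell's total. This was checked at all 69176581 nonzero entries, each within a tolerance of 0.001. All values below were computed from the count table. Gene positions came from GENCODE vM21 on GRCm38 (mm10), in which 14223 of the 14721 symbols matched 1 gene.

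Counts of all kept cells were summed per library and divided by the library total to give counts of UMIs per 1000000 UMIs (CPM). Ratios between libraries carry an exact conditional binomial 95% interval, levels an exact Poisson interval and shares of cells an exact Clopper-Pearson interval. With 1 library per genotype there are no replicates, no test was made between genotypes, and all intervals cover counting error only. Genes were counted as at least 1.5-fold higher or lower when their mean over the pair was at least 20 CPM. A count of 0 allows up to 3 counts of the library total, which is 0.0350 CPM in WT, 0.0296 in KO and 0.0273 in DKO.

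The gene groups, marker lists, comparisons, naming rule for genes and a set of alternatives were fixed before the data were examined. There were 20 gene groups and 13 marker lists. A member was measured when its mean over the pair was at least 5 CPM. The median log2 ratio of each list was placed among 10000 random lists matched for size and mean level, and the resulting percentile describes these libraries only. Some genes sit on more than 1 list. The genes named were the 10 highest and 10 lowest ratios of each pair at a mean of at least 20 CPM, leaving out predicted, ribosomal, mitochondrial, globin and sex-linked genes, the up to 4 members of each group with the largest ratios, and Spop and Myd88. Other genes are named as chosen after their values were seen. Some genes that this rule picks are not reported here.

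Cells of all 3 libraries were clustered together on log-normalized counts, using 2000 variable genes without sex-linked, mitochondrial, ribosomal or cell cycle genes, 30 principal components, 20 neighbours and the Leiden method at resolution 1. A cluster took a class name when at least 3 markers of 1 list were among its top 15 genes with a lead of at least 2 over the next list. This naming rule was set after the clusters had been seen. Class names end in "-like" because they rest on transcripts alone. No batch correction was applied, since library and genotype are the same thing in this design. Values within a class were compared where both libraries had at least 50 cells. For shares of cycling cells, each cell was thinned to 5500 UMIs and called cycling when S phase genes, or G2 and M phase genes, made up over 1% of its UMIs. Thinning left out 683 WT, 0 KO and 178 DKO cells with fewer UMIs.

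Doublets were scored with Scrublet in scanpy. Its automatic calls covered 0.135% of WT, 0.813% of KO and 0.183% of DKO cells, too few to be usable, so all cells were kept. An alternative removed the 531 WT, 194 KO and 536 DKO cells with the highest scores, at 0.8% per 1000 cells.

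Alternatives were scaling by edgeR's TMM, by median-of-ratios size factors or by a total without the most abundant genes, other level and size thresholds, equal weight for each cell, equal depth, quality and doublet filters, leaving out clusters of types outside the LSK gate, standardising to the WT cluster shares, pooled members, other clusterings, and other cycling thresholds and depths. Leaving out erythroid, neutrophil and B lineage classes, leaving out the clusters led by immediate early genes, and using the megakaryocyte-progenitor-like class alone were chosen after seeing the data.

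The procedure was tested on simulated data with the depths of KO and WT, where 200 of the genes were changed. Of 25 genes set at 0.25-fold, 23 were counted (92%), and of 25 each at 0.5-fold, 2-fold and 4-fold, 25 were. None of 50 genes at 0.8-fold, of 50 at 1.25-fold or of 5040 unchanged genes were. The 95% interval held the true ratio for 190 of the 200 changed genes. Of 100 unchanged lists, 2 fell outside percentiles 2.5 to 97.5. All 3000 simulated cells of 5 classes were returned to their class. These simulations held counting error alone, around the WT profile or around the profiles of clusters found here. They had no library effect and no cells outside the 5 classes. They therefore check the calculations and do not show how well counts or class names hold in the real libraries.

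The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, R 4.3.3, edgeR 4.0.16 and matplotlib 3.10.9.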

Results

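The data are UMI counts from 3 libraries of LSK cells, 1 each from WT, KO and DKO mice, and they address whether SPOP, the substrate receptor of a CUL3 ubiquitin ligase, restrains blood cell production through MyD88, the adaptor of Toll-like and interleukin-1 receptors. The WT library held 8147 cells and 85700749 UMIs (median 9245 per cell, range 3716 to 30936). The KO library held 4920 cells and 101393024 UMIs (median 17319, range 6053 to 57689). The DKO library held 8184 cells and 109920419 UMIs (median 12404.5, range 4255 to 40447). Median genes detected per cell were 2672, 3744.5 and 3307, and median mitochondrial shares were 3.05%, 2.84% and 2.67%.

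Transcripts of the targeted genes were examined first. Myd88 (chromosome 9, 119335934 to 119341411, GRCm38) stood at 13.7 counts per 1000000 (CPM) in WT (95% interval 12.9 to 14.5), 25.8 in KO (24.9 to 26.8) and 4.47 in DKO (4.08 to 4.88). It was 1.89-fold higher in KO than in WT (1.76 to 2.03) and 5.78-fold lower in DKO than in KO. Spop (chromosome 11, 95414080 to 95493406) stood at 70.7 (68.9 to 72.5), 63.1 (61.6 to 64.7) and 77.1 (75.4 to 78.7). These are 3' tags and the deleted part of Spop is not given, so Spop levels do not test the deletion. Some Myd88 tags remained in DKO, at 0.327 times the WT level (0.294 to 0.364), and absence of Myd88 there is by the genotype label. The ligase partner Cul3 was at 35.0, 41.7 and 27 CPM and the paralogue Spopl at 15.2, 14.2 and 13.6. The X-inactivation transcript Xist was at 0.187 in WT, 0 in KO and 1537 in DKO, while the Y-linked Ddx3y was at 43.9, 32.2 and 0. The DKO cells therefore came from female and the WT and KO cells from male animals, and sex is tied to genotype in both DKO comparisons.

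The KO and WT libraries were compared to ask what Spop deletion does to LSK cells. Among the largest ratios were granule protease and erythroid transcripts, higher in KO, and B lineage and immediate early transcripts, lower in KO. The neutrophil progenitor gene Ms4a3 was 33.0-fold higher (31.5 to 34.7), the protease gene Elane 16.4-fold, Ctsg 9.07-fold and Mpo 5.84-fold. The haptoglobin gene Hp (35.8-fold), the iron-chelating Lcn2 (25.9-fold), the myeloid receptor Trem3 (38.3-fold) and the chemokine receptor Ccr2 (27.4-fold) were also higher. Erythroid genes followed, with Tspo2 44.2-fold, the carbonic anhydrase Car1 16.5-fold and the transcription factor Klf1 10.2-fold higher. The metallothioneins Mt1 (19.9-fold) and Mt2 (18.1-fold) and the epidermal gene Dmkn (41.4-fold) completed the 10 highest.

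Among the 10 lowest ratios were genes of the pre-B-cell receptor and its signalling: Vpreb3 was 169-fold lower in KO (130-fold at the nearer bound), Cd79a 132-fold, Igll1 101-fold, Vpreb1 42.8-fold and Blnk 29.7-fold. The B lineage transcription factor Ebf1 was 110-fold lower, the early lymphoid Ly6d 40.4-fold, Mzb1 25.9-fold and Bfsp2 20.7-fold. The immediate early receptor Nr4a1 was 17.2-fold lower. The chemokine genes Ccl4 and Ccl3, which are NF-kB targets, were 12.1-fold and 11.7-fold lower, Fos 9.63-fold and Egr1 8.96-fold.

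Of 5141 genes, 455 were at least 1.5-fold higher and 630 at least 1.5-fold lower in KO than in WT. The all-gene median log2 ratio was 0.02 with library totals and 0.17 with TMM, and TMM gave 892 higher and 414 lower.

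Stem cell regulators had a median log2 KO/WT ratio of -1.14, with 21 of 30 measured members at least 1.5-fold lower, 0 higher and 9 within 1.5-fold. Cdkn1c, a cell cycle inhibitor of quiescent stem cells, was 5.22-fold lower. Lymphoid priming genes had a median of -1.79 (19 of 21 lower, 0 higher), led after Ebf1 by the interleukin-7 receptor Il7r (17.3-fold lower) and Ltb (9.63-fold). Immediate early genes had a median of -1.72 (23 of 27 lower, 1 higher). NF-kB targets had a median of -0.65 (13 of 24 lower, 5 higher). The Toll-like and interleukin-1 receptor components had a median of -0.22 (5 of 17 lower, 0 higher), including Il18r1 (3.51-fold lower) and the inhibitory receptor Sigirr (2.17-fold lower). Percentiles were 0 for the first 4 of these lists and 35.8 for the receptor components.

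Interferon-stimulated genes lay the other way, with a median of 0.31 at percentile 100 (11 of 40 higher, 2 lower, 27 within), which was 0.46 with TMM and 0.61 standardised to the WT cluster shares. The surface antigen Ly6c2 was 12.9-fold higher and the nucleic acid sensor Zbp1 4.25-fold. Ly6c2 is also a monocyte-dendritic marker and a top gene of a cluster with 28.5% of KO and 0.258% of WT cells. Its ratio may therefore follow the mix of cells. Megakaryocyte and erythroid priming genes had a median of 1.47 (14 of 24 higher, 2 lower). The azurophil granule list had a median of 0.50 (5 of 12 higher, 1 lower) and the specific granule list 0.52 (9 of 19 higher, 1 lower), including the oxidase subunit Cybb at 21.8-fold. Oxidative phosphorylation genes had a median of 0.48 (12 of 36 higher, 0 lower), with Uqcrq 2.24-fold and Cycs 2.03-fold higher. Heat shock genes had a median of 0.56 (8 of 17 higher, 2 lower), among them the endoplasmic reticulum chaperones Hspa5 (1.90-fold) and Hsp90b1 (1.88-fold).

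The cell cycle lists differed less, at 0.10 for S phase (40 of 42 within 1.5-fold) and 0.30 for G2 and M phase (45 of 52 within). Glycolysis and hypoxia genes had a median of 0.18, with Pgam1 2.14-fold and Ldha 1.98-fold higher and Ddit4 3.15-fold lower. MHC class II genes had a median of -0.65 (5 of 9 lower), with H2-Ob 5.52-fold lower, and MHC class I genes -0.03. The SPOP and CUL3 ligase list had a median of 0.19 and SPOP substrates -0.29, where Erg was 3.09-fold lower and Myd88 the single member at least 1.5-fold higher. Median and pooled values differed in sign for myeloid regulators (median 0.23, pooled -0.13) and p53 targets (median -0.35, pooled 0.56, where Cdkn1a was 2.88-fold lower). Standardised to the WT cluster shares, several of these medians took the other sign, at 0.045 for NF-kB targets, -0.074 for azurophil granule, -0.13 for specific granule, -0.063 for G2 and M phase, -0.11 for heat shock and 0.65 for MHC class II genes. Others came much closer to 0, at -0.21 for stem cell regulators, -0.18 for lymphoid priming, -0.22 for immediate early and 0.21 for megakaryocyte and erythroid priming genes. That setting used 7 clusters with 32.0% of WT and 45.0% of KO cells. It left out the stem-cell-like, erythroid-progenitor-like and B-lineage-like clusters described below and those led by immediate early genes. The neutrophil-progenitor-like cluster was weighted by its 21 WT cells. Smaller or reversed medians for lists of such cells were thus partly built in.

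Marker lists followed the same lines. KO/WT medians were 2.47 for erythroid and 2.47 for neutrophil progenitors, 1.84 for mature neutrophils, 0.98 for basophil-mast progenitors, 0.47 for megakaryocyte progenitors and 0.11 for monocyte-dendritic progenitors. They were -1.95 for lymphoid-primed cells, -6.66 for the B lineage, -1.36 for 3 measured T, NK and innate lymphoid markers and -1.77 for stem cells, although stem cell markers pooled gave 0.46. Eosinophil and macrophage lists had 0 measured members and the endothelial and stromal list 1.

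**Figure D1:**
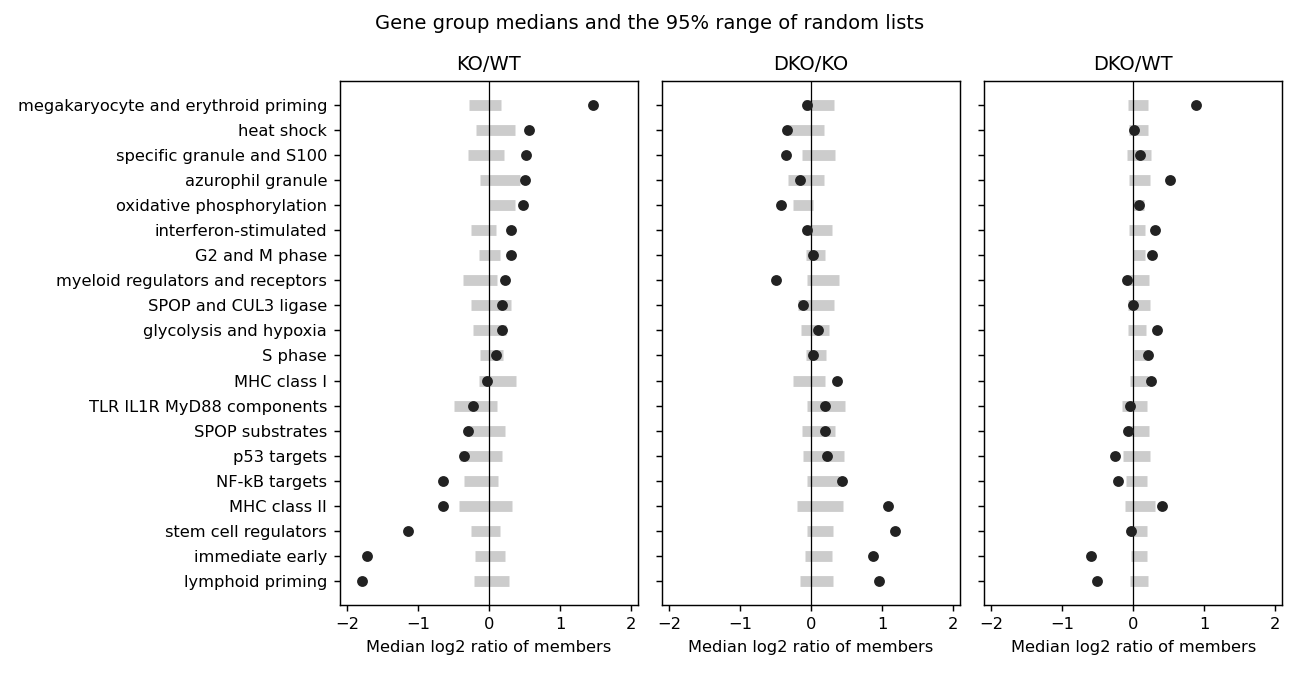
Median log2 ratio of the measured members of each gene group (horizontal axis) for KO/WT, DKO/KO and DKO/WT, beside the 95% range of random lists matched for size and level. Immediate early genes lie at -1.72 in KO/WT and 0.87 in DKO/KO.

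Cells were then grouped into classes to ask which kinds of cell each library held. Neutrophil-progenitor-like cells made up 28.5% of KO (27.3 to 29.8), 0.258% of WT and 0.562% of DKO. Their cluster also carried monocyte-dendritic markers, 3 among its top 10 genes against 4 of its own. Erythroid-progenitor-like cells made up 20.1% of KO (18.9 to 21.2), 0.0368% of WT and 0.0244% of DKO. Mature-neutrophil-like cells were 0.0982%, 0.935% and 0.208% of WT, KO and DKO. In KO they held more neutrophil progenitor transcripts than the neutrophil-progenitor-like class, with Elane at 13249 against 2275 CPM and Mpo at 4943 against 2031. The name, taken from the marker list, thus does not show that these cells were mature. B-lineage-like cells made up 8.09% of WT (7.51 to 8.70), 0.0610% of KO and 0.159% of DKO. Stem-cell-like cells were 8.74% of WT, 0.346% of KO and 3.67% of DKO, and lymphoid-primed-like cells 8.67%, 1.59% and 4.23%, where the WT share was 35.7% at resolution 0.6 and 25.4% at 1.5. Megakaryocyte-progenitor-like cells were 6.85% (6.31 to 7.42), 9.29% (8.49 to 10.1) and 13.6% (12.9 to 14.4).

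The remaining 67.3% of WT, 39.2% of KO and 77.5% of DKO cells fell in clusters without a name, several of them almost wholly from 1 library. A cluster mostly of 1 library, such as the erythroid-like cluster with 99.5% of its cells from KO, may be that library and not a cell type. One of the clusters without a name held 32.1% of KO cells and drew 98.3% of its cells from KO. Its top 15 genes included 2 stem cell markers, Ifitm1 and Ly6a. Ly6a is also on the interferon-stimulated list, as are Ifi27l2a and Rtp4 of the same top genes, so these do not show that the cluster holds stem cells. Whether the low stem-cell-like share of KO depends on the naming rule stays open. With clusters made from WT cells alone, neutrophil-progenitor-like cells were 32.3% of KO, against 22% at resolution 0.6, 18.0% at 1.5 and 24.5% with cell cycle genes, and stem-cell-like cells were 2.66% of KO and 7.17% of DKO. With cell cycle genes among the variable genes, stem-cell-like cells were 16.6% of WT. All libraries are of LSK-sorted cells per the labels, depth per cell differed between libraries, and the shares are of sorted cells and not of marrow.

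**Figure D2:**
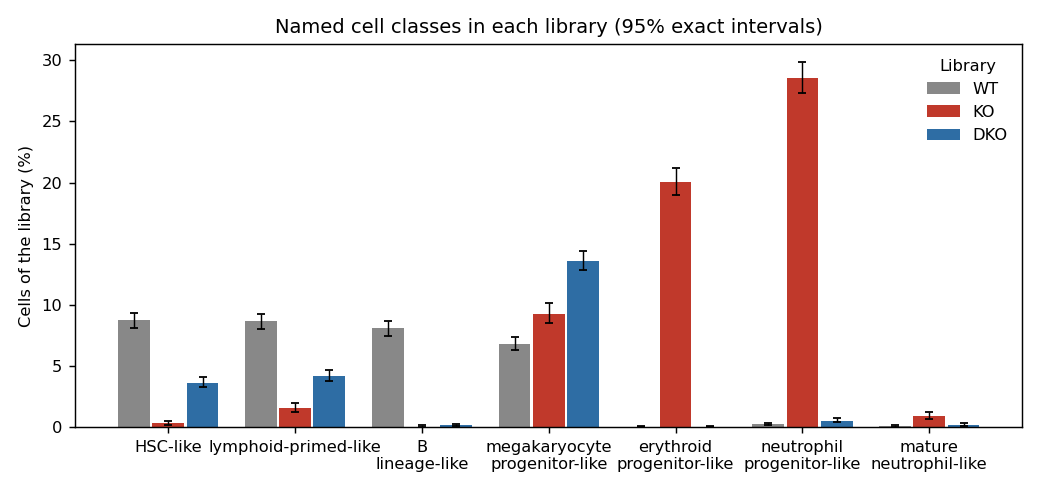
Share of each library's cells (vertical axis, percent) in the named classes for WT, KO and DKO, with exact 95% intervals for counting error. Neutrophil-progenitor-like cells reach 28.5% in KO and erythroid-progenitor-like cells 20.1%.

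Class-by-class values were set side by side to ask what differed between cells of the same class. In megakaryocyte-progenitor-like cells (558 WT, 457 KO, 1114 DKO), interferon-stimulated genes kept a KO/WT median of 0.40 (13 of 39 higher, 0 lower). Immediate early genes stood at -0.70 (15 of 24 lower, 1 higher), stem cell regulators at -0.53 (12 of 31 lower, 0 higher) and NF-kB targets at -0.27 (5 of 19 lower, 2 higher). In lymphoid-primed-like cells (706 WT, 78 KO), interferon-stimulated genes stood at 0.54 (19 of 39 higher, 0 lower), but immediate early genes at -0.17 and NF-kB targets at 0.10. Ly6a, which encodes the Sca-1 antigen used for sorting, was 2.26-fold higher in KO than in WT among megakaryocyte-progenitor-like cells (1.91 to 2.69) and 2.85-fold among lymphoid-primed-like cells (2.48 to 3.27), against 90.4 and 85.1 CPM in the whole libraries. Kit, the other sorting antigen, was 2.18-fold lower in KO megakaryocyte-progenitor-like cells. Myd88 was 1.69-fold higher (1.29 to 2.23) there. In lymphoid-primed-like cells the KO/WT ratios were 0.805 (0.565 to 1.12) for Kit and 1.43 (0.848 to 2.30) for Myd88, and both intervals included a ratio of 1.

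Other genes of the megakaryocyte-progenitor-like class were chosen after their values were seen. Platelet genes Pf4 (3.73-fold), Gp1bb (2.45-fold) and Itgb3 (2.02-fold), Mt1 (5.14-fold) and the interferon-induced Ifitm3 (1.76-fold) were higher in KO, and Fos (3.27-fold), Jun (2.5-fold) and Apoe (2.31-fold) were lower. At a mean of at least 50 CPM, 33 of 2581 genes were at least 1.5-fold higher and 51 lower in this class, against 297 and 242 of 2542 in the whole libraries. Elane stood at 35.2 CPM in this class in KO, 32.9 in erythroid-progenitor-like and 29.1 in lymphoid-primed-like cells. Free RNA gives such a like level across types, so granule levels within classes are open to it.

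**Figure D3:**
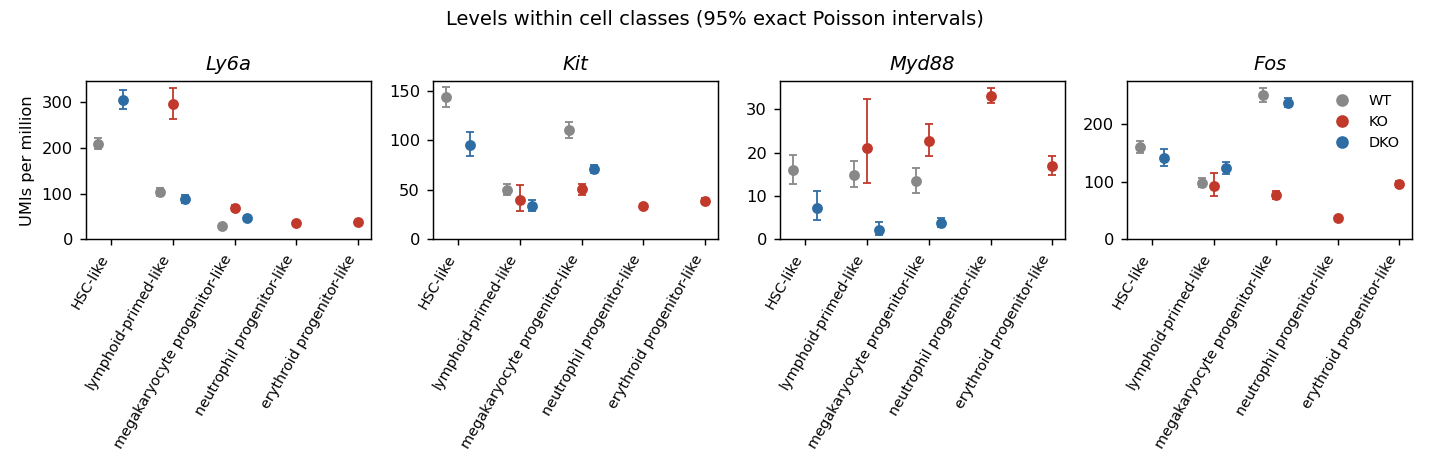
CPM of single genes (vertical axis) within cell classes for WT, KO and DKO, with exact 95% Poisson intervals. Ly6a in megakaryocyte-progenitor-like cells is 29.9 in WT, 67.7 in KO and 46.9 in DKO.

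The DKO and KO libraries were compared to ask which differences of the KO library need Myd88. Genes higher in KO than in WT were among the lowest here: Dmkn was 18.2-fold lower, Lcn2 13.8-fold, Tspo2 13.1-fold, Trem3 11.6-fold, Ccr2 9.94-fold, Ms4a3 8.20-fold, the erythroid Ermap 7.85-fold and Igsf6 7.38-fold. Sapcd1 (7.36-fold) and Bex4 (7.14-fold) completed the 10 lowest. The chemokine genes Ccl5 (8.95-fold higher, 8.10 to 9.92), Ccl3 (7.31-fold) and Ccl4 (6.93-fold), the G protein regulator Rgs1 (7.65-fold), Fos (6.02-fold) and the quiescence factor Klf2 (5.80-fold) were among the 10 highest with a mean of at least 20 CPM, below which Nr4a1 was 12.6-fold higher. Stxbp4 (6.82-fold), Myl10 (5.67-fold), the B cell receptor partner Cd72 (5.13-fold) and Gimap6 (4.86-fold) were the others.

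Of 5163 genes, 693 were at least 1.5-fold higher and 311 lower in DKO than in KO, with an all-gene median of 0.08. With TMM, that median was -0.12 and the split was 372 higher and 676 lower. Stem cell regulators had a median of 1.19 (21 of 29 higher, 0 lower), including Mecom (4.21-fold) and Angpt1 (3.83-fold). Lymphoid priming genes had a median of 0.95 (11 of 18 higher), with Flt3 2.98-fold and Sox4 3.01-fold higher. Immediate early genes had a median of 0.87 (17 of 26 higher), NF-kB targets 0.44 (9 of 23 higher, 3 lower) and MHC class II genes 1.09 (8 of 9 higher). MHC class I genes had a median of 0.36, with the peptide transporter Tap2 2.27-fold higher. Lower lists were myeloid regulators (-0.50; 9 of 23 lower, 4 higher; Id1 6.77-fold lower), oxidative phosphorylation (-0.43; 9 of 36 lower, 0 higher), specific granule (-0.35; 9 of 19 lower, 1 higher) and heat shock genes (-0.34, pooled 0.00; 5 of 15 lower, 3 higher). Azurophil granule genes, at -0.15, lay inside the range of random lists (percentile 25.1; 5 of 12 lower, 2 higher), although Elane was 6.20-fold lower. Interferon-stimulated genes had a median of -0.06 (2 of 40 higher, 7 lower), but of -0.25 with TMM and -0.35 standardised to the WT cluster shares, with Isg15 2.22-fold lower. Megakaryocyte and erythroid priming genes split, with 8 higher, 11 lower and a median of -0.05. S phase (0.03), G2 and M phase (0.02), glycolysis and hypoxia (0.09, pooled -0.29), receptor components (0.19), SPOP substrates (0.20), the ligase list (-0.11) and p53 targets (0.23, mean -0.01, pooled -0.66) had small medians or mixed signs. Standardised to the WT cluster shares, lymphoid priming (-0.012), specific granule (0.32), heat shock (0.088) and MHC class II genes (-0.32) took the other sign. Stem cell regulators (0.012), NF-kB targets (0.0093) and immediate early genes (0.098) fell close to 0. These values rest on the same 7 clusters and few KO cells as in KO/WT. The clusters led by immediate early genes and the stem-cell-like, erythroid-progenitor-like and B-lineage-like clusters were again left out. In settings chosen after seeing the data, myeloid regulators took the other sign: 0.12 without the erythroid, neutrophil and B lineage classes and 0.46 in the megakaryocyte class.

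The DKO and WT libraries were compared to ask what remains when both genes are affected. Of the measured B lineage markers, 8 of 8 were lower in DKO too, and genes on and off that list led the low ratios: Igll1 and Ebf1 were each 70.1-fold lower than in WT, Cd79a 66.2-fold, Vpreb3 52.1-fold, Mzb1 40.9-fold, Blnk 27.9-fold, Vpreb1 27.4-fold, Ly6d 21.4-fold and Bfsp2 9.90-fold. The recombinase gene Rag1 was 71.4-fold lower. Among the 10 highest ratios were Cpa3 at 4.71-fold (4.43 to 5.01), Pf4 at 3.23-fold, Itga2b at 3.18-fold and Mcpt8 at 2.71-fold. Of the megakaryocyte progenitor markers 6 of 10 were at least 1.5-fold higher, and of the basophil-mast markers 3 of 6, with 0 lower in either list. Car1 (4.27-fold), Ms4a3 (4.03-fold), Ccl5 (3.49-fold), Mt1 (3.04-fold), Ctsg (2.91-fold) and Elane (2.65-fold) were also higher.

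Of 5307 genes, 129 were at least 1.5-fold higher and 99 lower, with an all-gene median of 0.09. With TMM, the split was 98 higher and 117 lower. Megakaryocyte and erythroid priming genes had a median of 0.89 (12 of 20 higher, 0 lower), azurophil granule genes 0.52 (4 of 12 higher, 0 lower), MHC class II genes 0.40 (2 of 9 higher; H2-Eb1 2.04-fold and H2-Aa 1.95-fold higher), glycolysis 0.33, interferon-stimulated genes 0.30 (6 of 39 higher, 0 lower), G2 and M phase 0.26, MHC class I 0.25 and S phase 0.21. Immediate early genes had a median of -0.59 (14 of 27 lower, 0 higher), lymphoid priming genes -0.51 (11 of 23 lower), p53 targets -0.25 and NF-kB targets -0.22 (8 of 24 lower, 3 higher). In settings chosen after seeing the data, NF-kB targets were at 0.088 without immediate early clusters and 0.11 in the megakaryocyte class, where p53 targets were at 0.0069. Standardised to the WT cluster shares, megakaryocyte and erythroid priming came to 0.21 and immediate early genes to -0.21. Stem cell regulators were at -0.04 (27 of 31 within 1.5-fold), with Slamf1 2.31-fold higher. The other lists lay between -0.10 and 0.10.

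The KO and DKO differences from WT were set against each other to ask how far loss of Myd88 brings the KO profile back. Of the 1085 genes at least 1.5-fold different in KO, DKO was closer to WT than to KO for 81.4%, and the median of the DKO difference over the KO difference was 0.215. The share was 77.1% for the 455 genes higher in KO and 84.4% for the 630 lower. These genes were picked by their KO/WT ratio, so a peculiarity of the KO library would also place DKO nearer to WT. No chance value was computed for the share, so it does not measure an effect of Myd88 alone. B lineage genes were exceptions. Higher in both KO and DKO were 34 genes and lower in both were 64, but both lists share the WT library, and a peculiarity of that library would enter both. Across 5003 genes, which are not independent replicates, the differences had a correlation of 0.562 and a covariance of 0.117. Simulated unchanged libraries sharing the WT library gave 0.552 and 0.000488, which allows for counting error alone. With the WT cells split at random into 2 sets, 1 for each difference, the values were 0.561 and 0.117. Shared counting error thus explains little of either, but a peculiarity of the WT library would remain in both sets. Without the erythroid, neutrophil and B lineage classes, an alternative chosen after seeing the data, the share was 61.8% of 346 genes and the median fraction 0.375.

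Cycling was compared at 1 depth. At 5500 UMIs per cell, 12.6% of WT (11.8 to 13.4), 15.3% of KO (14.3 to 16.4) and 18.2% of DKO cells (17.4 to 19.1) passed the threshold. With 0.5% in place of 1%, KO was highest (35.9%, 58.2% and 46.3%), and with 2% KO was lowest (0.697%, 0.183% and 0.899%), so the order of the libraries depends on the threshold, and free RNA stays open for such calls.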

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

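Every test of the erythroid and neutrophil progenitor pattern and the class mix tests of the immediate early pattern were chosen only after the results were seen, and the bounds of the neutrophil doublet, neutrophil free RNA and Sca-1 tests, and of the share near Myd88, were set with their values known. The other tests were set beforehand.

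Xist stood at 1537 CPM in DKO against 0.187 in WT, a signal outside the planned comparisons which shows that the animals differed in sex. The MHC class II median was -0.65 in KO/WT and 0.40 in DKO/WT, opposite directions whose difference was not tested. Standardised to the WT cluster shares, which used 7 clusters with 32.0% of WT and 45.0% of KO cells, the KO/WT median was 0.65 and the DKO/KO median -0.32. Within classes, KO/WT was -0.99 in lymphoid-primed-like cells (5 of 9 lower, 0 higher) and 0.28 in megakaryocyte-progenitor-like cells, so the direction differed with the cells compared.

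Of the KO cells, 48.6% were erythroid-progenitor-like or neutrophil-progenitor-like, against 0.295% in WT. As shares of cells these need no scaling between libraries, which argues against scaling as the source of these classes. The sizes of the gene ratios were not tested in this way. Free RNA was also argued against, since Hba-a1 in the other KO cells was 0.261% of its level in the erythroid class, and Elane 2.84% of its level in the neutrophil class (or 20.9% with mature-neutrophil-like cells, which hold it themselves). Doublets were argued against for the erythroid class, whose median UMIs were 0.786 times those of other KO cells. The neutrophil class had 2.33 times the UMIs. It had 30.5 cells (22.8 to 41.9) for each cell of the single other KO cluster with such levels of its markers. Random pairing gives at most 2 with doublets in 50% of droplets, which argues against doublets as the source of the whole class. The presence of some doublets stays open. Of its 14 measured markers, 0 stood above that other cluster (median ratio 0.315, 0.204 to 0.401), as dilution in doublets would also give. Cells lacking Ly6a that slipped through the sort were argued against by a level of 39.5% (37.4 to 41.7) of the WT library in the class with less of it. A candidate explanation is that KO progenitors carry more Sca-1 and so enter the gate, which needs more Ly6a in KO cells of the same class. Ly6a was at least 2.26-fold higher (1.91 to 2.69) in the 2 classes compared, megakaryocyte-progenitor-like and lymphoid-primed-like cells. DKO/WT ratios of Ly6a were 1.57 (1.34 to 1.85) and 0.848 (0.746 to 0.963) there, and 1.46 (1.33 to 1.59) in stem-cell-like cells. DKO held only 0.0244% erythroid-like and 0.562% neutrophil-like cells, so more Ly6a did not always come with such cells. The gate also needs Kit, whose KO/WT ratio was 0.459 (0.403 to 0.523) in megakaryocyte-progenitor-like cells and 0.805 (0.565 to 1.12) in lymphoid-primed-like cells. The erythroid and neutrophil classes themselves, with 3 and 21 WT cells, could not be compared, and surface protein was not measured.

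Immediate early genes were lower in KO, and NF-kB targets mostly so, with 13 of 24 lower and 5 higher. A different mix of classes was argued against as the whole cause for immediate early genes, which had a median of -0.70 (-1.16 to -0.40) within megakaryocyte-progenitor-like cells. Lymphoid-primed-like cells, with -0.17 (-0.35 to 0.040), leave it room as part of the cause. The median of -0.22 when standardised to WT cluster shares, against -1.72, cannot decide this. That setting left out the clusters led by immediate early genes, which held 1772 WT and 36 KO cells, so a smaller median was built in. For NF-kB targets a different mix stays open, at -0.27 (-0.45 to 0.20) in megakaryocyte-progenitor-like cells. The standardised 0.045 cannot weigh it either, since the left-out clusters led by immediate early genes had members of this list, such as Zfp36, among their top genes. Also open is the part of immediate early members in the NF-kB list, since the 18 others had a median of -0.39 (-1.12 to 0.25). Handling of the cells, to which such genes respond, cannot be told apart from genotype with 1 library each: the share of cells with over 0.5% immediate early UMIs was 3.43 times as high in WT as in KO among megakaryocyte-progenitor-like cells but 0.801 times among lymphoid-primed-like cells, where 2 of 78 KO (2.56%, 0.312 to 8.96) and 13 of 633 WT cells are too few to weigh against it.

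There were 74 genes at least 1.5-fold apart in DKO from both other libraries, 58 higher and 16 lower, among them Cpa3 and Gata2 higher and Scd2 lower, chosen after their values were seen. Genes of the sex chromosomes were argued against as the source, making up 2.70% of them (0.329 to 9.42), but autosomal effects of sex were not tested. DNA within 10 Mb of Myd88 was argued against as the source of most of the set, holding 0 of the 74 genes (0 to 4.86%). Only 32 tested genes lay there, and the interval of the enrichment, 0 to 7.36 times, is too wide to decide whether such genes were enriched. The enrichment of 2.88 times (0.792 to 7.12) near Spop decides nothing either. By label KO and DKO carry the same Spop allele, whose flanking DNA should not set them apart. A different mix of classes stays open too, since 34.4% (22.9 to 47.3) of the 64 genes measurable in megakaryocyte-progenitor-like cells kept the difference there. Absence of Myd88 is the design's biological explanation and was not tested apart from sex.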

How the results depend on the processing

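The settings without erythroid, neutrophil and B lineage classes, without immediate early clusters and with the megakaryocyte class alone were chosen after seeing the data, and the others were planned. No paired analysis was possible because there was 1 library per genotype. Of 60 group medians, the quality filter and the removal of high doublet scores each kept 60 within their spread, both scalings 51, equal cell mix 29, the megakaryocyte class 37 and the off-type removal 46. The mature neutrophil class was not found in clusters from WT cells. Unless stated, the cause was not tested. Depth limits the low genes: with no minimum but 1 UMI in both libraries, many more genes passed.

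Counts are given as higher and lower. In KO/WT they were 892 and 414 with TMM, 949 and 390 with median of ratios, 297 and 242 at a mean of 50, 108 and 213 at a ratio of 2, 1280 and 3615 with no minimum, 72 and 102 standardised to WT cluster shares, 82 and 134 in the megakaryocyte class, and 85 and 261 without the erythroid, neutrophil and B lineage classes. Without genes over 0.5% of UMIs, 962 were lower. In DKO/KO they were 372 and 676 with TMM, 369 and 695 with median of ratios, 275 and 193 at a mean of 50, 202 and 84 at a ratio of 2, 3597 and 1136 with no minimum, 284 and 103 standardised, 326 and 82 in the megakaryocyte class, and 322 and 55 without the off-type classes. In DKO/WT they were 62 and 45 at a mean of 50, 22 and 32 at a ratio of 2, 1047 and 1238 with no minimum, and 61 and 40 standardised, with 40 lower in the megakaryocyte class and 170 lower without the most abundant genes. A higher minimum and a larger ratio give fewer genes by construction.

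Under TMM, the interferon-stimulated median was 0.46 in KO/WT and -0.25 in DKO/KO, Spop was 68.4 CPM in KO and 73.0 in DKO, and Myd88 28.0 in KO. With median of ratios, the interferon-stimulated medians were 0.48 and -0.26.

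Standardised to WT cluster shares, which used 7 clusters with 32.0% of WT, 45.0% of KO and 41.3% of DKO cells for the KO comparisons, several directions reversed. Among these clusters, those with 617 and 655 WT cells held only 26 and 24 KO cells. Not among them were the clusters led by immediate early genes and the stem-cell-like, erythroid-progenitor-like and B-lineage-like clusters. In KO/WT, medians were 0.045 for NF-kB targets, -0.074 for azurophil granule, -0.13 for specific granule, -0.063 for G2 and M phase, -0.11 for heat shock and 0.65 for MHC class II, all reversed. In DKO/KO the reversed ones were -0.012 for lymphoid priming, 0.32 for specific granule, 0.088 for heat shock and -0.32 for MHC class II. Others shrank or moved: in KO/WT, 0.61 for interferon-stimulated, -0.21 for stem cell regulators, -0.18 for lymphoid priming, 0.21 for megakaryocyte and erythroid priming and -0.22 for immediate early genes. In DKO/KO they were 0.0093 for NF-kB targets, -0.35 for interferon-stimulated, 0.012 for stem cell regulators and 0.10 for immediate early genes. In DKO/WT they were 0.21 for megakaryocyte and erythroid priming and -0.21 for immediate early genes.

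In the megakaryocyte class, reversed medians were 0.11 for NF-kB targets in DKO/WT, -0.52 and 0.63 for specific granule in KO/WT and DKO/KO (free RNA was not removed there), -0.054 and 0.46 for myeloid regulators, 0.0069 for p53 targets in DKO/WT and 0.28 for MHC class II in KO/WT. Smaller ones were -0.53 and 0.26 for stem cell regulators, -0.26 and 0.40 for lymphoid priming, 0.34 for megakaryocyte and erythroid priming in DKO/WT, and -0.70 in KO/WT and -0.093 in DKO/WT for immediate early genes. Without the erythroid, neutrophil and B lineage classes, specific granule was -0.28 and 0.33 and myeloid regulators -0.23 and 0.12, all reversed, while stem cell regulators were -0.50 and 0.34 and lymphoid priming -0.78 and 0.24. Without immediate early clusters, NF-kB targets reversed to 0.088 in DKO/WT and immediate early genes were -0.62 in KO/WT and -0.23 in DKO/WT. Myeloid regulators in KO/WT reversed to -0.20 with members at 20 CPM and to -0.13 pooled, heat shock in DKO/KO to 0.0045 pooled, and specific granule in DKO/KO to 0.18 without clusters outside the gate.

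The share of KO/WT genes with DKO closer to WT was 84.6% at a mean of 50, 86.6% at a ratio of 2, 70.7% standardised, 68.5% in the megakaryocyte class and 61.8% without the off-type classes.

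Class shares moved with the clustering. Thinned first, stem-cell-like cells were 10.7%, 2.52% and 5.50% of WT, KO and DKO, lymphoid-primed-like cells 17.4%, 0.752% and 3.56%, and megakaryocyte-progenitor-like cells 5.83% of WT. With clusters from WT cells, B-lineage-like cells were 5.41% of WT, stem-cell-like cells 2.66% of KO and 7.17% of DKO, megakaryocyte-progenitor-like cells 6.11% of WT and 12.0% of KO, and neutrophil-progenitor-like cells 32.3% of KO. At resolution 0.6, lymphoid-primed-like cells were 35.7%, 1.99% and 6.68%, megakaryocyte-progenitor-like cells 12.8% of KO and 14.9% of DKO, and neutrophil-progenitor-like cells 22% of KO. At resolution 1.5, B-lineage-like cells were 5.38% and stem-cell-like cells 11.9% of WT, lymphoid-primed-like cells 25.4% of WT and 4.80% of DKO, and neutrophil-progenitor-like cells 18.0% of KO. With cell cycle genes, stem-cell-like cells were 16.6% of WT, erythroid-progenitor-like cells 22.7% of KO, lymphoid-primed-like cells 18.8% of WT and 5.19% of DKO, megakaryocyte-progenitor-like cells 6.14% of WT and 11.1% of KO, and neutrophil-progenitor-like cells 24.5% of KO.

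Cycling shares were 35.9%, 58.2% and 46.3% of WT, KO and DKO at over 0.5% of UMIs, and 0.697%, 0.183% and 0.899% at over 2%. A lower threshold passes more cells by construction.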

Other observations

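The single genes and single clusters given here were chosen after the results were seen. Group medians within clusters were planned, but the rule that names the classes was set after the clusters had been seen. Interferon-stimulated genes had KO/WT medians of 0.40 in megakaryocyte-progenitor-like cells (13 of 39 higher, 0 lower) and 0.54 in lymphoid-primed-like cells (19 of 39 higher, 0 lower), whereas immediate early genes stood at -0.70 and -0.17. Ifi27l2a, an interferon-induced gene, was 2.33-fold higher (1.75 to 3.14) in KO than in WT megakaryocyte-progenitor-like cells and 3.12-fold (2.67 to 3.65) in lymphoid-primed-like cells. Its DKO/WT ratios were 0.895 (0.668 to 1.21) and 1.2 (1.05 to 1.37). Over all cells the interferon-stimulated list had a median of 0.30 in DKO/WT and 0.31 in KO/WT, so this 1 gene does not stand for the list. In stem-cell-like cells (300 DKO, 712 WT), the DKO/WT median of interferon-stimulated genes was 0.39, with 10 of 41 members at least 1.5-fold higher and 0 lower, and Ly6a was 1.46-fold higher. The opposite stood in 1 cluster without a class name, which drew 93.9% of its cells from DKO (1472 DKO, 85 WT), with a median of -1.14, 33 of 44 members lower and 0 higher. MHC class II genes stood at 0.75 in DKO/WT stem-cell-like cells, with 5 of 9 higher.

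Megakaryocyte-progenitor-like cells of DKO differed from both other libraries in the mast cell protease gene Cpa3 (87.4 CPM, against 28.5 in WT and 17.6 in KO). Pf4, a platelet granule gene, was at 486 CPM in WT, 1810 in KO and 896 in DKO in that class. Cells with over 0.5% immediate early UMIs made up 22.8% of WT, 3.21% of KO and 14.3% of DKO, and a cluster led by such genes drew 96.2% of its 1562 cells from WT. Another drew 96.0% of its 1201 cells from DKO, and a further one was mixed, with 60.9% of its 616 cells from DKO.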
